A study of Mus musculus with 105 samples.

How the data were processed

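Poly(A) RNA of mouse embryonic stem cells was sequenced in 5 datasets of 1 series, 105 samples in 35 groups of 3. The labels describe culture in serum with LIF for the fusion panel and both RBBP5 datasets and give no medium for the other 2. Counts were available for 93 libraries in 31 groups. The other 12 samples, given the KDM4 inhibitor QC6352, had no column in any count table, so their 6 planned comparisons were not run.

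The deposited values of all 5 datasets are raw read counts per gene. Per the submitters' processing notes, the fusion panel and the RBBP5 dataset with the SUV2 fusion were trimmed with Trim Galore 0.4.5, aligned with STAR 2.4 to mm10 and counted with HTSeq 0.9.1, and the notes also name Picard and DESeq2. The RBBP5 dataset with the SD2 fusion used Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.8 and DESeq2 1.46.0. For the SUZ12 degron and the HP1 dataset the notes name Trimmomatic and HISAT2 and no counting tool. Tables of counts that the authors had divided by 1 size factor per library were multiples of the raw counts and were not used. The panel's columns were matched to groups by inference from their wording: VEFS was read as S12N, which labels call dVEFS, VSET as S12N-SD2, DVFullH2 as S12N-SUV2 and E14JU as wild type. The panel and the RBBP5 dataset with SUV2 list 53656 gene symbols, of which 27 were turned into dates and left as they stand. The other 3 datasets list 27179 Entrez identifiers, 25275 of which matched a symbol. Gene positions are those of the GENCODE annotation of GRCm38, the assembly of mm10.

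Library totals ranged from 8.80 to 29.97 M counts in the panel, from 18.59 to 22.26 M in the RBBP5 dataset with SUV2, from 11.44 to 17.78 M in the RBBP5 dataset with SD2, from 8.31 to 18.81 M in the degron dataset and from 5.48 to 21.72 M in the HP1 dataset. Differences between datasets in library preparation and counting make levels comparable only within a dataset.

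Each dataset was fitted on its own with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr by group, a model of group means and the quasi-likelihood F test. This left 16230 genes for the panel, 15757 and 15211 for the RBBP5 datasets with SUV2 and with SD2, 14016 for the degron and 14026 for the HP1 dataset. The common biological coefficient of variation was 0.0767, 0.0281, 0.0881, 0.169 and 0.0707 in the same order. P-values were adjusted by Benjamini and Hochberg over the genes of each comparison, with a threshold of 0.05, and tests were two-sided. Each ± after a log2 fold change is the standard error, computed from the unshrunk fold change and its F value, with n = 3 per group, and each ± after a level in CPM, counts scaled by library size, is the standard deviation. Where a group had 0 counts of a gene in all libraries, the fold change was bounded with a floor of 3 counts over the group. Where a group had under 30, the ± would understate counting error, so in comparisons of group pairs the 95% counting interval stands in its place, and with 3 or fewer the fold is the ratio of scaled counts. The labels speak of biological triplicates except in the RBBP5 dataset with SD2. Nothing says its cultures were separate, so its p-values measure only spread between samples. Each genotype or construct is its own line, so its effect is confounded with line differences.

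The comparisons, 25 gene lists and the rule for naming genes were fixed before the data were examined. The rule took Suz12, Rbbp5, Setd2, Suv39h1, Suv39h2, Cbx5 and Kdm4a to Kdm4d, the 5 higher and 5 lower genes with the largest change (2 and 2 in secondary comparisons) among those past the threshold with a mean log2 CPM of at least 1 and all 3 libraries of 1 group above all 3 of the other, without predicted or unnamed genes, and up to 4 members of each list with the smallest p. Not every gene it took is printed: left out are most whose call an alternative ended, some others, and 1 gene not reported here. Other genes are said to be chosen after their values were seen. The lists hold developmental transcription factors bound by PRC2, Hox genes, PRC2-bound signalling genes, pluripotency, primed, germline, 2-cell, primitive endoderm, mesoderm, neural, trophoblast and fibroblast markers, imprinted genes, interferon-stimulated genes, PRC2 subunits, COMPASS subunits, writers and readers of H3K9 and H3K36 methylation, p53 targets, stress-response genes, ribosomal proteins, cell-cycle genes, cholesterol synthesis, glycolysis and hypoxia genes, genes of the mitochondrial genome and Y-linked genes. A further list, called Suz12-responsive here, was drawn from a knockout in another dataset of the series, so no library was both used to choose it and tested with it. For tests in the panel, both RBBP5 datasets and the degron dataset it holds the 1429 genes at least 2-fold higher in the HP1 dataset's knockout. For tests in the HP1 dataset it holds the 2246 genes at least 2-fold higher in the panel's knockout.

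List medians are over measured members. Lists were tested with limma's camera 3.58.1 at an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over 781 tests. Where a list's adjusted p is given alone and passes the threshold, the call also held with an estimated correlation. Overlaps of calls between comparisons were tested with Fisher's exact test against the genes tested in both. Alternatives were RLE size factors, no filter on low counts, a term for the replicate number, DESeq2 1.42.0, each library left out in turn, the Suz12-responsive list without its 2-fold requirement, and further settings chosen after seeing the data. Other splits of the compared libraries were counted.

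The fit was tested on data simulated on each dataset. Of 100 genes at log2 fold 1 it recovered 83% for the panel's knockout, 89% and 86% for RBBP5 loss with SUV2 and SD2. For 2 h in the degron it was 64% and for the HP1 dataset's knockout 80%. At 0.5 it recovered 57%, 76%, 62%, 5% and 63%. Of calls 0.71%, 7.3%, 3.27%, 4.17% and 8.33% were false, 7.3% and 8.33% above the threshold. Figures were drawn with matplotlib 3.10.9.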

Results

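The series measured expression in mouse embryonic stem cell lines whose histone modifications had been changed, and its stated subject is the genes repressed by PRC2, the Polycomb complex that methylates histone H3. The fusion panel held wild type, a Suz12 knockout, and the knockout with wild-type SUZ12 or with S12N, which is SUZ12 without its VEFS domain. It also held the knockout with S12N fused to SUV2, to SD2, or to versions of either that the titles call dead. The labels do not spell out SUV2 and SD2. In the RBBP5 dataset with SUV2, a line with FKBP-tagged RBBP5 (R), the same with a Suz12 knockout (RS) and RS with S12N-SUV2 received dTAG13, a degrader of the tagged protein, or DMSO for 24 h. The RBBP5 dataset with SD2 had the same design with S12N-SD2 and 500 nM of the degrader. In the degron dataset SUZ12 carried an auxin-inducible tag, and cells received 50 µM auxin (IAA) for 2, 4, 8, 24 or 48 h or DMSO for 48 h. The HP1 dataset held wild type, the Suz12 knockout, and the knockout with full-length SUZ12, with S12N or with S12N fused to the chromodomain of HP1a. Every group had 3 libraries.

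Suz12, on chromosome 11 from 79993106 to 80034123, was read first in every group. In the panel it averaged 294 ± 24.3 CPM in wild type and 56 ± 10.6 in the knockout. It reached 269 ± 35.7 with wild-type SUZ12 and 298 ± 62.9 with S12N. The dead SUV2 fusion had 237 ± 28 CPM and the active one 181 ± 15.1. The dead SD2 fusion had 222 ± 29.9 and the active one 114 ± 10.5. In the RBBP5 dataset with SUV2, R had 384 ± 4.42 CPM in DMSO and 386 ± 12.3 in dTAG13, RS had 32 ± 1.22 and 36.4 ± 1.18, and RS with S12N-SUV2 had 101 ± 1.76 and 90 ± 2.34. In the one with SD2, R had 325 ± 1.73 CPM in DMSO and 294 ± 46.1 in dTAG-13, RS had 59.3 ± 3.62 and 71.5 ± 2.92, and RS with S12N-SD2 had 80 ± 3.25 and 92.4 ± 1.49. The degron cells, in which the protein is the target, had 184 ± 23.5 CPM in DMSO and 193 ± 22.4, 188 ± 4.21, 173 ± 16.7, 136 ± 64.3 and 202 ± 3.76 after 2, 4, 8, 24 and 48 h. In the HP1 dataset wild type had 296 ± 12.7 CPM, the knockout 61.2 ± 5.43, and the knockout 169 ± 4.32 with full-length SUZ12, 119.9 ± 4.77 with S12N and 98.2 ± 4.52 with the HP1 fusion.

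**Figure D1:**
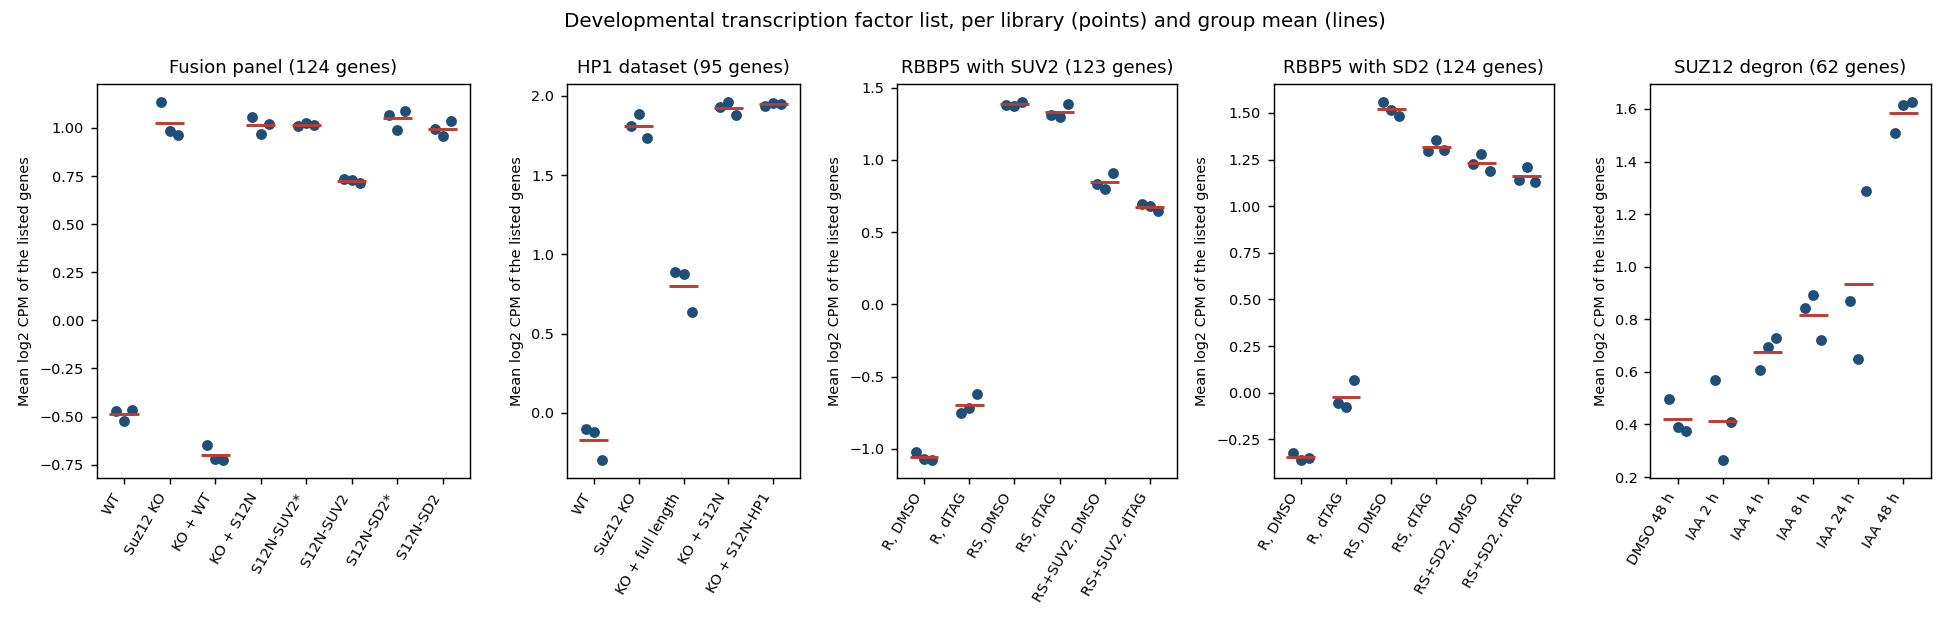
Mean log2 CPM of the developmental transcription factor list (y axis) in each library (points) with the group mean (lines), by group and dataset. All 3 knockout libraries lie above all 3 wild-type libraries in the panel and in the HP1 dataset, and the 3 libraries with wild-type or full-length SUZ12 lie below those of the knockout.

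The knockout of the panel was set against wild type to find the genes that change without SUZ12. Fmr1nb (6.19, 5.48 to 7.04), the proteoglycan gene Srgn (5.67, 4.66 to 7.04), Hoxa10 (5.44, 4.61 to 6.47), the collagen genes Col4a2 (5.53 ± 0.29) and Col4a1 (4.96 ± 0.23) rose. Fmr1nb lies on chromosome X from 68761839 to 68804567 and Hoxa10 on chromosome 6 from 52231197 to 52240854. Gna14 (-4.59 ± 0.22), the homeobox gene Nkx6-3 (-3.71 ± 0.18), Frem2 (-3.64 ± 0.24), Sp5 (-3.49 ± 0.29) and the eye and neural regulator Pax6 (-3.31 ± 0.19) fell. Of 124 developmental transcription factors measured, 89 rose and 9 fell (94 and 10 adjusted over the list alone), with Meis2 (3.08 ± 0.12) and Foxd1 (4.13, 3.45 to 4.94) among them. Their median was 1.91, or 1.82 with absent members at their bound (adjusted p = 4.42e-13). Of 26 Hox genes measured, 25 rose and 0 fell (26 and 0 adjusted over the list alone), with Hoxd13 (3.88 ± 0.16) and Hoxa11 (6.48, 4.92 to 8.76) among them. Their median was 4.01, or 3.21 with absent members at their bound (adjusted p = 1.82e-14). Of 29 PRC2-bound signalling genes measured, 19 rose and 2 fell (20 and 2 adjusted over the list alone), with Cdkn2a (3.66 ± 0.18) and Fgf10 (2.66 ± 0.14) among them. Their median was 1.48 (adjusted p = 6.99e-05). Of 1316 Suz12-responsive genes measured, 1104 rose and 21 fell (1137 and 24 adjusted over the list alone). Their median was 1.55 (adjusted p = 4.08e-55). In all 7638 genes passed, 3867 higher and 3771 lower, with 2246 and 361 at 2-fold or more.

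Markers of other cell types also moved in this knockout. Of 23 primitive endoderm markers measured, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with Col4a1 (4.96 ± 0.23) and Col4a2 (5.53 ± 0.29) among them. Their median was 2.94 (adjusted p = 2.06e-12, adjusted p = 0.0821 with an estimated correlation). Of 24 germline genes measured, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with Sohlh2 (4.12 ± 0.14) and Mael (2.66 ± 0.12) among them. Their median was 2.04, or 1.96 with absent members at their bound (adjusted p = 1.36e-12). Of 17 2-cell genes measured, 17 rose and 0 fell (17 and 0 adjusted over the list alone). Their median was 7.29, or 4.05 with absent members at their bound (adjusted p = 1.12e-12). The 2-cell genes are multi-copy, and how reads were shared between copies is not known. Of 16 mesoderm genes measured, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with Lefty2 (1.54 ± 0.09) and Evx1 (2.47 ± 0.31) among them. Their median was 1.18 (adjusted p = 0.00464, adjusted p = 0.0695 with an estimated correlation). Of 9 fibroblast genes measured, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Thy1 (3.06 ± 0.20) and Loxl1 (3.40, 2.77 to 4.13) among them. Their median was 1.85 (adjusted p = 0.00305, adjusted p = 0.062 with an estimated correlation). Of 12 PRC2 subunit genes measured, 7 fell and 2 rose (7 and 2 adjusted over the list alone), with Suz12 (-2.39 ± 0.15) and Rbbp4 (-0.45 ± 0.06) among them. Their median was -0.24 (adjusted p = 0.0441, adjusted p = 0.11 with an estimated correlation). Of 24 H3K9 and H3K36 methylation writers and readers measured, 17 fell and 0 rose (19 and 0 adjusted over the list alone), with Ehmt1 (-0.62 ± 0.06) and Cbx1 (-0.56 ± 0.06) among them. Their median was -0.26 (adjusted p = 6.73e-05). Of 24 cell-cycle genes measured, 18 fell and 0 rose (19 and 0 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.00238, adjusted p = 0.432 with an estimated correlation). Of 17 cholesterol synthesis genes measured, 10 fell and 0 rose (11 and 0 adjusted over the list alone). Their median was -0.31 (adjusted p = 0.00247, adjusted p = 0.445 with an estimated correlation). No shift passed for the pluripotency genes (median -0.17 over 24, mean 0.05 with a test pointing down, adjusted p = 0.511), primed markers (median -0.16 over 14, adjusted p = 0.746) and neural genes (median 0.20 over 15, adjusted p = 0.963). Nor did one pass for the imprinted genes (median 0.16 over 28, adjusted p = 0.869), interferon-stimulated genes (median 0.39 over 13, adjusted p = 0.257) and COMPASS subunit genes (median -0.18 over 17, adjusted p = 0.257).

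The HP1 dataset gave a second reading of SUZ12 loss. Fmr1nb (7.83, 6.72 to 9.57), Hoxa10 (6.88, 5.75 to 8.33), Srgn (5.79, 4.74 to 7.12), the endocytic receptor gene Cubn (5.60, 4.74 to 6.60) and the neuronal gene Stmn2 (5.51 ± 0.10) rose. Napsa (-3.73 ± 0.20), Crocc2 (-2.69 ± 0.20), Pak6 (-2.60 ± 0.29), Igfals (-2.45 ± 0.34) and Nkx6-3 (-2.45 ± 0.12) fell. Among 95 developmental transcription factors measured, 72 rose and 4 fell (78 and 4 adjusted over the list alone), with Meis2 (3.89 ± 0.17) and Foxd1 (4.71 ± 0.20) among them. Their median was 2.36 (adjusted p = 2.86e-16). Among 22 Hox genes measured, 22 rose and 0 fell (22 and 0 adjusted over the list alone). Their median was 6.00, or 4.37 with absent members at their bound (adjusted p = 5.98e-15). Among 23 primitive endoderm markers measured, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with Col4a1 (3.64 ± 0.11) and Col4a2 (3.91 ± 0.14) among them. Their median was 3.75 (adjusted p = 8.28e-20). Among 22 germline genes measured, 17 rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 1.48 (adjusted p = 1.43e-08). Of 14 primed markers measured, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with Zic2 (1.87 ± 0.10) and Otx2 (1.54 ± 0.10) among them. Their median was 0.57 (adjusted p = 0.000125). In all 5867 genes passed, 3111 higher and 2756 lower, with 1429 and 239 at 2-fold or more. Of the genes higher in the panel's knockout, 1931 were higher here too against 706.5 expected (odds ratio 15.5). Of the lower ones, 1760 were shared against 714.3 expected (odds ratio 10.7).

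Wild-type SUZ12 was returned to the knockout in the panel. Srgn (-5.91, -6.83 to -5.19), Hoxd13 (-4.78 ± 0.15), the growth factor receptor gene Pdgfra (-4.54, -5.20 to -3.98), Cubn (-4.51, -5.15 to -3.97) and Fbp2 (-4.34 ± 0.23) fell. Gna14 (4.37 ± 0.22), Nkx6-3 (3.79 ± 0.17), Frem2 (3.78 ± 0.24), the interferon-inducible Gbp2b (4.07, 3.46 to 4.72) and Gbp2 (4.04 ± 0.32) rose. Within 124 developmental transcription factors measured, 101 fell and 6 rose (101 and 6 adjusted over the list alone), with Meis2 (-3.29 ± 0.10) and Foxd1 (-5.62, -6.55 to -4.90) among them. Their median was -2.10 (adjusted p = 5.46e-20). Within 26 Hox genes measured, 26 fell and 0 rose (26 and 0 adjusted over the list alone). Their median was -5.35, or -4.52 with absent members at their bound (adjusted p = 4.82e-19). Within 23 primitive endoderm markers measured, 21 fell and 1 rose (21 and 1 adjusted over the list alone), with Col4a1 (-4.24 ± 0.20) and Sox7 (-2.43 ± 0.12) among them. Their median was -2.80 (adjusted p = 4.4e-12, adjusted p = 0.087 with an estimated correlation). Among 1316 Suz12-responsive genes measured, 1030 fell and 62 rose (1053 and 71 adjusted over the list alone). Their median was -1.30 (adjusted p = 1.35e-41). In all 7897 genes passed, 3964 higher and 3933 lower, with 595 and 2051 at 2-fold or more. Wild-type and knockout libraries of the panel (8.80 to 10.7 M counts) were shallower than those of its other lines (17.04 to 29.97 M) and their columns are named differently, so a batch between them is confounded with lines compared across it. S12N against the knockout also crosses it, with 619 genes and a transcription factor median of -0.02, so a batch shared by the deeper libraries does not give this fall.

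Against wild type, the knockout with wild-type SUZ12 still differed. Wnt4 (3.03, 2.37 to 3.78) and the keratin gene Krt19 (2.79 ± 0.28) were higher, and the forebrain gene Emx2 (-2.94 ± 0.31) and the noncoding Halr1 (-2.25 ± 0.21) were lower. Of all 124 developmental transcription factors measured, 14 fell and 3 rose (15 and 4 adjusted over the list alone). Their median was -0.38 (adjusted p = 0.000867). Of all 26 Hox genes measured, 3 fell and 0 rose (5 and 0 adjusted over the list alone). Their median was -0.99, or -0.87 with absent members at their bound (adjusted p = 0.000801). Of 15 trophoblast markers measured, 6 rose and 0 fell (7 and 1 adjusted over the list alone), with Krt8 (2.35 ± 0.19) and Krt18 (2.15 ± 0.18) among them. Their median was 0.68 (adjusted p = 4.74e-06). Within 1316 Suz12-responsive genes measured, 224 rose and 36 fell (261 and 47 adjusted over the list alone). Their median was 0.25, or 0.24 with absent members at their bound (adjusted p = 8.01e-08). In all 1687 genes passed, 920 higher and 767 lower, with 313 and 67 at 2-fold or more. Without the filter on low counts 1154 were higher and 533 lower, in DESeq2 889 and 979, and without replicate 2 of the rescued line 1054 passed.

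Full-length SUZ12 was returned to the knockout of the HP1 dataset. Napsa (3.58 ± 0.20), Frem2 (2.96 ± 0.27), Gna14 (2.81 ± 0.25), the neuronal filament gene Ina (2.39 ± 0.10) and Crocc2 (2.38 ± 0.20) rose. Pkd1l2 (-2.38 ± 0.39), Slfn9 (-2.36 ± 0.37), Fetub (-2.25 ± 0.19), Osr2 (-2.18 ± 0.34) and the neurofilament gene Nefm (-2.14 ± 0.44) fell. Among all 95 developmental transcription factors measured, 47 fell and 2 rose (52 and 2 adjusted over the list alone), with Foxd1 (-2.05 ± 0.14) and Meis2 (-1.61 ± 0.12) among them. Their median was -1.19 (adjusted p = 1.87e-11). Among all 22 Hox genes measured, 17 fell and 0 rose (18 and 0 adjusted over the list alone). Their median was -1.73 (adjusted p = 2.65e-08). Within 22 germline genes measured, 12 fell and 1 rose (13 and 1 adjusted over the list alone). Their median was -0.83 (adjusted p = 1.22e-06). Of all 1509 Suz12-responsive genes measured, 784 fell and 1 rose (864 and 3 adjusted over the list alone). Their median was -0.94 (adjusted p = 5.01e-36). In all 3707 genes passed, 1728 higher and 1979 lower, with 144 and 682 at 2-fold or more.

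S12N without a fused domain was compared with the knockout. In the panel Suz12 (2.41 ± 0.15) was higher. So were the ribosomal RNA genes n-R5-8s1 (5.70 ± 1.02), Rn18s-rs5 (4.82 ± 0.74) and the noncoding Rn7sk (3.55, 2.96 to 4.15), RNAs that poly(A) selection removes. Usp26 (-1.63 ± 0.27), the 2-cell gene Usp17le (-1.36 ± 0.26), Rhox5 (-1.29 ± 0.17), the Y-linked Uty (-1.56 ± 0.14) and Ddx3y (-1.35 ± 0.09) fell. Of 124 developmental transcription factors measured, 4 rose and 0 fell (3 and 0 adjusted over the list alone), with Foxd1 (0.93 ± 0.15) and Meis2 (0.37 ± 0.08) among them. Their median was -0.02, their mean -0.04, and the test pointed up (adjusted p = 0.839). Among all 1316 Suz12-responsive genes measured, 99 fell and 10 rose (145 and 16 adjusted over the list alone). Their median was -0.16 (adjusted p = 2.08e-06, adjusted p = 0.0756 with an estimated correlation). Among 17 2-cell genes measured, 6 fell and 0 rose (15 and 0 adjusted over the list alone). Their median was -1.24 (adjusted p = 8.08e-14). Of 40 ribosomal protein genes measured, 24 rose and 0 fell (37 and 0 adjusted over the list alone). Their median was 0.22 (adjusted p = 4.07e-31). In all 619 genes passed, 308 higher and 311 lower, with 62 and 67 at 2-fold or more. Without the filter on low counts 494 were higher and 319 lower. The count was 346 without replicate 1 of S12N, 332 without replicate 1 of the knockout and 351 without its replicate 3.

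In the HP1 dataset Suz12 (0.99 ± 0.06) and Tex13b (2.05 ± 0.31) were higher with S12N than in the knockout, and Zfp951 (-1.99 ± 0.26) and the Y-linked Ddx3y (-11.25, -16.56 to -8.77) were lower. Ddx3y lies on chromosome Y from 1260771 to 1286629. Eif2s3y, also Y-linked, changed by at least -9.15. Among 95 developmental transcription factors measured, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.14 (adjusted p = 0.119). Of 1509 Suz12-responsive genes measured, 28 fell and 9 rose (38 and 12 adjusted over the list alone). Their median was -0.02 (adjusted p = 0.573). Of all 22 germline genes measured, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with Sohlh2 (-0.69 ± 0.08) and Dazl (-0.79 ± 0.15) among them. Their median was -0.25 (adjusted p = 0.000188). In all 265 genes passed, 108 higher and 157 lower, with 3 and 24 at 2-fold or more. Without the filter on low counts 172 were higher and 163 lower. The count was 134 without replicate 1 or without replicate 3 of the knockout, and 162, 129 and 165 without replicates 1, 2 and 3 of S12N. In both datasets 14 genes were higher with S12N against 1.7 expected (adjusted p = 1.3e-09, Fisher's exact test), and 26 were lower against 3 expected (adjusted p = 3.39e-17).

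The active SUV2 fusion was compared with its dead version in the panel. The angiogenic receptor gene Flt1 (-3.28 ± 0.29), Srgn (-3.26 ± 0.26), the hormone receptor gene Pth1r (-3.23 ± 0.28), Foxq1 (-3.22 ± 0.26) and the endocytic adaptor gene Dab2 (-3.15 ± 0.23) fell. Calml4 (1.99 ± 0.17), Gab1 (1.96 ± 0.07), Nlrp4f (1.81 ± 0.12), Crocc2 (1.79 ± 0.18) and the vitamin C transporter gene Slc23a1 (1.76 ± 0.17) rose. Of all 23 primitive endoderm markers measured, 20 fell and 0 rose (22 and 0 adjusted over the list alone), with Sox17 (-2.90 ± 0.24) and Col4a1 (-2.17 ± 0.18) among them. Their median was -2.28 (adjusted p = 2.23e-23). Within 17 2-cell genes measured, 17 fell and 0 rose (17 and 0 adjusted over the list alone). Their median was -5.36, or -4.58 with absent members at their bound (adjusted p = 5.93e-28). Among all 24 germline genes measured, 15 fell and 2 rose (17 and 3 adjusted over the list alone), with Mael (-1.26 ± 0.09) and Stag3 (-1.18 ± 0.10) among them. Their median was -0.70 (adjusted p = 3.66e-07, adjusted p = 0.0723 with an estimated correlation). Among 1316 Suz12-responsive genes measured, 604 fell and 73 rose (677 and 93 adjusted over the list alone). Their median was -0.42 (adjusted p = 3.96e-19). Within 124 developmental transcription factors measured, 25 fell and 12 rose (27 and 12 adjusted over the list alone). Their median was -0.12 (adjusted p = 0.122). No shift passed for the Hox genes (median -0.29 over 26, adjusted p = 0.0691). -0.39 ± 0.13 was the change of Suz12, whose call ended without replicate 1 of the dead line (-0.29) or replicate 1 or 2 of the active line (-0.35 and -0.37). In all 3676 genes passed, 1593 higher and 2083 lower, with 120 and 835 at 2-fold or more. After thinning all libraries of the panel to the same depth 2334 passed.

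The dead SUV2 fusion was also set against S12N. Suv39h2 (1.88 ± 0.07) was higher and n-R5-8s1 (-6.50 ± 1.00) and Rn18s-rs5 (-4.60 ± 0.73) lower. Among all 23 primitive endoderm markers measured, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with Dab2 (1.56 ± 0.21) and Sox17 (1.52 ± 0.22) among them. Their median was 0.94 (adjusted p = 3.63e-10, adjusted p = 0.119 with an estimated correlation). Of all 124 developmental transcription factors measured, 18 rose and 13 fell (18 and 14 adjusted over the list alone). Their median was -0.02 (adjusted p = 0.705). Within 1316 Suz12-responsive genes measured, 256 rose and 71 fell (271 and 79 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.0157, adjusted p = 0.35 with an estimated correlation). Without replicate 3 of S12N that call ended (median 0.12). In all 3411 genes passed, 1942 higher and 1469 lower, with 165 and 210 at 2-fold or more. Without replicate 1 of the dead fusion 2251 passed.

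The active SD2 fusion was compared with its dead version. B3glct (-4.80 ± 0.18), Miip (-3.54 ± 0.13), Zfp869 (-2.57 ± 0.14), Klf12 (-2.36 ± 0.17) and the activin antagonist gene Fst (-1.71 ± 0.22) fell. Arl14epl (2.05 ± 0.13), Tuba3a (1.86 ± 0.11), the imprinted Sfmbt2 (1.76 ± 0.12), Rhox5 (1.52 ± 0.15) and Nos3 (1.52 ± 0.20) rose. Among all 124 developmental transcription factors measured, 7 rose and 7 fell (3 and 5 adjusted over the list alone), with Foxd1 (-1.18 ± 0.15) and Nkx6-2 (0.70 ± 0.14) among them. Their median was -0.07, their mean -0.07, and the test pointed up (adjusted p = 0.995). Of 24 germline genes measured, 10 rose and 0 fell (13 and 1 adjusted over the list alone), with Hormad1 (1.31 ± 0.13) and Meioc (0.81 ± 0.10) among them. Their median was 0.29 (adjusted p = 0.000165, adjusted p = 0.171 with an estimated correlation). Of all 1316 Suz12-responsive genes measured, 247 fell and 75 rose (266 and 85 adjusted over the list alone). Their median was -0.16 (adjusted p = 0.00196, adjusted p = 0.236 with an estimated correlation). Suz12 (-0.96 ± 0.14) was lower in the active line. No shift passed for the Hox genes (median -0.23 over 26, adjusted p = 0.257), primitive endoderm markers (median 0.01 over 23, mean -0.07 with a test pointing down, adjusted p = 0.711) and 2-cell genes (median -0.20 over 17, adjusted p = 0.539). In all 2927 genes passed, 1299 higher and 1628 lower, with 152 and 201 at 2-fold or more. The count was 1699 and 1884 without replicates 1 and 3 of the active line, 1746 without replicate 2 of the dead line and 1934 after thinning to the same depth.

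Against S12N the dead SD2 fusion had higher Zscan4d (2.23 ± 0.30), Usp17le (2.04 ± 0.22) and Setd2 (0.83 ± 0.06) and lower n-R5-8s1 (-6.85 ± 1.05) and Rn18s-rs5 (-4.94 ± 0.74). Of all 17 2-cell genes measured, 16 rose and 0 fell (17 and 0 adjusted over the list alone). Their median was 2.06 (adjusted p = 4.46e-21). Of 3 Y-linked genes measured, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 1.06 (adjusted p = 3.05e-08). No shift passed for the developmental transcription factors (median 0.02 over 124, adjusted p = 0.936) and Suz12-responsive genes (median 0.05 over 1316, adjusted p = 0.281). In all 2123 genes passed, 1132 higher and 991 lower, with 180 and 97 at 2-fold or more. Without the filter on low counts 878 were higher and 1178 lower. The count was 1371 without replicate 1 of the dead fusion and 1363 after thinning. The active SUV2 and SD2 fusions, each against its dead version, shared 161 higher genes against 127.5 expected (adjusted p = 0.00174, Fisher's exact test) and 230 lower genes against 208.9 (adjusted p = 0.101). More genes, 305 against 159.8 expected, were higher with SUV2 and lower with SD2 (adjusted p = 3.05e-31, Fisher's exact test, chosen after seeing the data), and 181 went the other way against 166.7 (adjusted p = 0.254).

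The chromodomain of HP1a fused to S12N was compared with S12N alone. The Y-linked Ddx3y (10.81, 8.33 to 16.11) was higher, as was Eif2s3y by at least 8.67, all Y-linked genes being close to 0 in the S12N line. Zfp951 (1.69 ± 0.26) was higher and Tex13b (-1.92 ± 0.30) and the surface antigen gene Ly6a (-1.05 ± 0.20) were lower. S12N against the knockout had Zfp951 at -1.99 and Tex13b at 2.05, so both genes ran back toward the knockout here. Of 23 primitive endoderm markers measured, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with Lamb1 (0.92 ± 0.07) and Lama1 (0.80 ± 0.08) among them. Their median was 0.75 (adjusted p = 4.51e-21). Of 18 p53 targets measured, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Ccng1 (0.53 ± 0.05) and Eda2r (0.65 ± 0.08) among them. Their median was 0.35 (adjusted p = 2.25e-11). Of 95 developmental transcription factors measured, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was -0.01, their mean 0.04, and the test pointed up (adjusted p = 0.985). Among all 1509 Suz12-responsive genes measured, 85 rose and 26 fell (88 and 26 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.0319, adjusted p = 0.131 with an estimated correlation). Without replicate 1 or 2 of the fusion that call ended (medians 0.10 and 0.12). In all 978 genes passed, 597 higher and 381 lower, with 41 and 6 at 2-fold or more. The count was 540 and 625 without replicates 1 and 2 of S12N, 430, 528 and 1492 without replicates 1, 2 and 3 of the fusion, and 1634 with replicates 1 and 2 only. With the active SUV2 fusion of the panel, 88 higher genes were shared against 63.3 expected (adjusted p = 0.00154, Fisher's exact test) and 37 lower genes against 48.2 (adjusted p = 0.0886). More, 137 against 75.8 expected, were lower with SUV2 and higher with the HP1 fusion (adjusted p = 1.44e-12, Fisher's exact test, chosen after seeing the data), and 40 went the other way against 40.2.

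**Figure D2:**
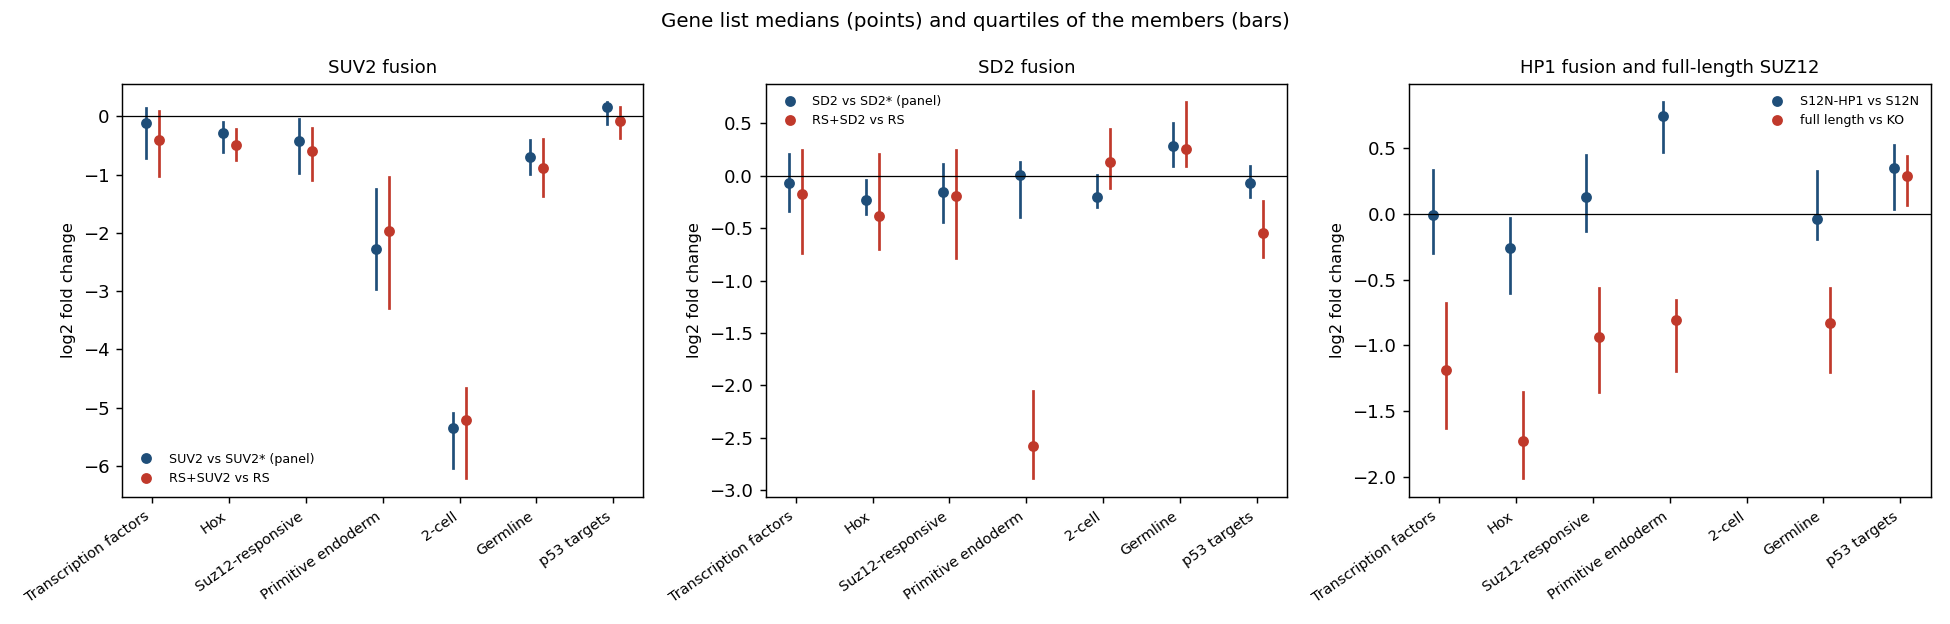
Median log2 fold change (y axis) of 7 gene lists (points) with the quartiles of their members (bars) for the SUV2 fusion, the SD2 fusion, and the HP1 fusion with full-length SUZ12. The primitive endoderm median lies at -2.28 for SUV2 in the panel and at 0.75 for the HP1 fusion, and the 2-cell list has no value in the HP1 dataset.

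In the RBBP5 datasets, RS was compared with R in DMSO. With SUV2, Cubn (7.10, 6.49 to 7.83), Pdgfra (5.93 ± 0.12), the growth factor gene Igf2 (6.55, 5.97 to 7.25), the regulators Hand1 (6.88, 6.11 to 7.88) and Gata6 (6.75, 6.17 to 7.45) rose. Napsa (-5.03 ± 0.13), Nkx6-3 (-4.51 ± 0.19), Suz12 (-3.59 ± 0.03), Krt17 (-3.53 ± 0.05) and Glod5 (-3.48 ± 0.16) fell. Among 123 developmental transcription factors measured, 109 rose and 3 fell (110 and 3 adjusted over the list alone), with Meis2 (3.95 ± 0.09) and Gata4 (5.46 ± 0.14) among them. Their median was 2.95 (adjusted p = 2.57e-16). Of 28 Hox genes measured, 28 rose and 0 fell (28 and 0 adjusted over the list alone). Their median was 5.66, or 4.90 with absent members at their bound (adjusted p = 6.35e-12). Among 17 trophoblast markers measured, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with Tfap2c (-1.84 ± 0.03) and Krt18 (3.53 ± 0.07) among them. Their median was 3.15 (adjusted p = 0.00138). In all 11314 genes passed, 5811 higher and 5503 lower, with 2632 and 628 at 2-fold or more. With the panel's knockout 2922 higher genes were shared against 1327.4 expected (odds ratio 14.8) and 2784 lower genes against 1347.8.

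In the dataset with SD2, Foxq1 (12.06, 9.58 to 17.37), Cubn (11.21, 10.34 to 12.40) and the endoderm regulator Sox17 (11.36, 8.88 to 16.66) rose in RS, and Srgn and Nxf7 were higher by at least 9.68 and 9.06. Napsa (-6.27 ± 0.23), Glod5 (-4.38, -5.13 to -3.75), Pax6 (-3.91 ± 0.11), the imprinted noncoding RNAs Meg3 (-11.10, -12.83 to -9.99) and Rian (-9.67, -10.55 to -8.99) fell. Meg3 lies on chromosome 12 from 109541001 to 109571726. Within 124 developmental transcription factors measured, 92 rose and 10 fell (92 and 11 adjusted over the list alone), with Gata6 (7.98, 7.40 to 8.68) and Gata4 (6.21 ± 0.14) among them. Their median was 1.96 (adjusted p = 2e-10). Among 33 Hox genes measured, 33 rose and 0 fell (33 and 0 adjusted over the list alone). Their median was 3.26 (adjusted p = 5.55e-11). In all 8976 genes passed, 4833 higher and 4143 lower, with 2628 and 741 at 2-fold or more. With the panel's knockout 2458 higher genes were shared against 1036.4 expected (odds ratio 15.4) and 2158 lower genes against 1015.1.

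**Figure D3:**
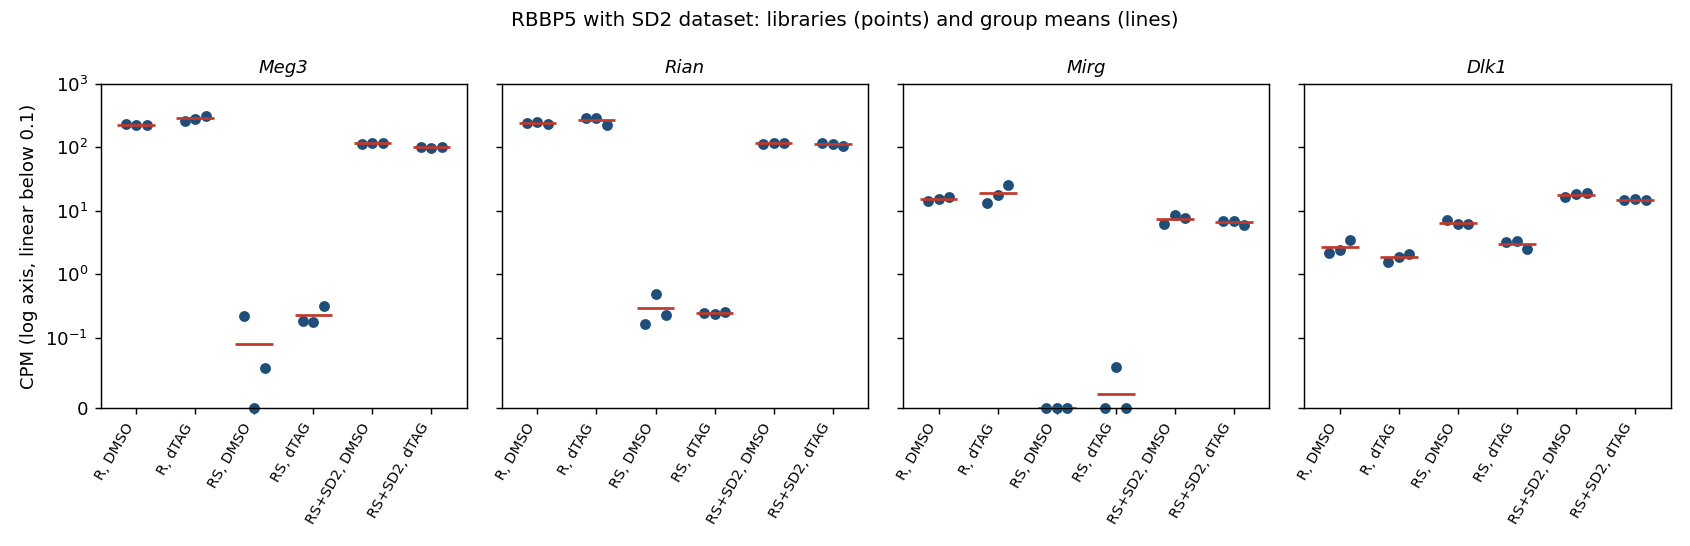
CPM of genes of the imprinted domain that holds Meg3 (y axis) in each library (points) of the RBBP5 dataset with SD2, by line and treatment. Meg3 has 4, 0 and 1 counts in the 3 RS libraries in DMSO.

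S12N-SUV2 was compared with RS in DMSO. Foxq1 (-4.14 ± 0.15), Klb (-3.93, -4.56 to -3.40), Pdgfra (-3.74 ± 0.09), Cubn (-3.73 ± 0.10) and Gata6 (-3.62 ± 0.09) fell. The Nodal antagonist gene Lefty1 (2.54 ± 0.11), Slc23a1 (2.31 ± 0.15), Vrtn (2.23 ± 0.18), Ripply1 (2.12 ± 0.16) and Gad1 (2.11 ± 0.13) rose. Among 23 primitive endoderm markers measured, 22 fell and 1 rose (22 and 1 adjusted over the list alone), with Col4a1 (-2.70 ± 0.04) and Col4a2 (-2.88 ± 0.05) among them. Their median was -1.97 (adjusted p = 7.87e-18). Among all 12 2-cell genes measured, 12 fell and 0 rose (12 and 0 adjusted over the list alone). Their median was -5.21, or -4.73 with absent members at their bound (adjusted p = 3.15e-08). Among 23 germline genes measured, 17 fell and 2 rose (17 and 2 adjusted over the list alone), with Mael (-1.50 ± 0.06) and Sohlh2 (-1.17 ± 0.05) among them. Their median was -0.89 (adjusted p = 2.68e-07). Of all 123 developmental transcription factors measured, 56 fell and 15 rose (57 and 15 adjusted over the list alone), with Sox17 (-3.40 ± 0.16) and Gata4 (-1.76 ± 0.08) among them. Their median was -0.40 (adjusted p = 0.00314, adjusted p = 0.0632 with an estimated correlation). Of 1276 Suz12-responsive genes measured, 862 fell and 77 rose (887 and 81 adjusted over the list alone). Their median was -0.60 (adjusted p = 4.97e-21). In all 7673 genes passed, 3676 higher and 3997 lower, with 175 and 989 at 2-fold or more.

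S12N-SD2 was compared with RS in DMSO. Suz12 (0.43 ± 0.09) was higher, and Setd2 (-0.01 ± 0.11, adjusted p = 0.961) did not pass. Meg3 (10.13, 9.02 to 11.86), Rian (8.61, 7.93 to 9.49), Ppp1r14d (2.15 ± 0.24), Zan (2.14 ± 0.19) and the calcium channel gene Cacna1h (2.03 ± 0.29) rose. Glipr1 (-3.93 ± 0.16), Hkdc1 (-3.75 ± 0.23), the small heat shock gene Cryab (-3.62 ± 0.14), Cdh6 (-3.57 ± 0.15) and Igf1 (-3.55 ± 0.17) fell. Within 23 primitive endoderm markers measured, 22 fell and 0 rose (22 and 0 adjusted over the list alone), with Col4a2 (-3.10 ± 0.05) and Serpinh1 (-2.67 ± 0.06) among them. Their median was -2.58 (adjusted p = 2.47e-28). Among 19 p53 targets measured, 13 fell and 0 rose (13 and 1 adjusted over the list alone), with Plk2 (-1.58 ± 0.08) and Ccng1 (-0.91 ± 0.06) among them. Their median was -0.55 (adjusted p = 8.87e-09). Within 23 germline genes measured, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Smc1b (1.35 ± 0.09) and Mov10l1 (0.85 ± 0.07) among them. Their median was 0.26 (adjusted p = 8.12e-05). Among 1390 Suz12-responsive genes measured, 500 fell and 186 rose (530 and 221 adjusted over the list alone). Their median was -0.19 (adjusted p = 3.96e-05). Among all 124 developmental transcription factors measured, 38 fell and 11 rose (38 and 12 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.0306, adjusted p = 0.0632 with an estimated correlation). Without replicate 1 of RS in DMSO the transcription factor call ended (median -0.10). In all 4257 genes passed, 1983 higher and 2274 lower, with 351 and 605 at 2-fold or more. Without the third dTAG-13 library of R in the fit 6652 passed.

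Loss of RBBP5, a subunit of the COMPASS methyltransferases, was read as dTAG13 against DMSO in each line. In R of the dataset with SUV2, the mucin gene Muc3 (2.84 ± 0.17), Mgat4c (2.28 ± 0.16), Bcl11a (1.94 ± 0.13), Fam63b (1.80 ± 0.18) and Zeb2 (1.79 ± 0.18) rose. Pdlim4 (-2.73 ± 0.17), Foxr1 (-2.49 ± 0.23), Sh3tc1 (-2.13 ± 0.13) and Acap1 (-2.10 ± 0.13) fell. Within 18 p53 targets measured, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with Ccng1 (0.58 ± 0.03) and Plk2 (0.72 ± 0.04) among them. Their median was 0.31 (adjusted p = 2.12e-08). Of all 23 germline genes measured, 13 rose and 3 fell (13 and 3 adjusted over the list alone). Their median was 0.37 (adjusted p = 0.00121, adjusted p = 0.111 with an estimated correlation). Of 123 developmental transcription factors measured, 33 rose and 9 fell (29 and 8 adjusted over the list alone), with En2 (1.36 ± 0.10) and Pou4f2 (0.65 ± 0.07) among them. Their median was 0.63, or 0.42 with absent members at their bound (adjusted p = 0.00555, adjusted p = 0.0753 with an estimated correlation). No shift passed for the Suz12-responsive genes (median -0.04 over 1276, adjusted p = 0.494). Of 7 mitochondrial genome transcripts measured, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.84 (adjusted p = 0.00171, adjusted p = 0.391 with an estimated correlation). In all 8134 genes passed, 3999 higher and 4135 lower, with 501 and 546 at 2-fold or more.

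In R of the dataset with SD2, Muc3 (2.68 ± 0.11), Mgat4c (2.45 ± 0.24), Mindy2 (2.33 ± 0.12), Zcwpw1 (2.24 ± 0.12) and Mxd4 (2.17 ± 0.13) rose. Acap1 (-2.84 ± 0.17), Grb7 (-2.83 ± 0.09), Slc18b1 (-2.69 ± 0.31), Mpzl2 (-2.66 ± 0.16) and Fcgrt (-2.63 ± 0.28) fell. Of all 19 p53 targets measured, 16 rose and 1 fell (16 and 1 adjusted over the list alone). Their median was 0.59 (adjusted p = 1.66e-07). Among 124 developmental transcription factors measured, 36 rose and 12 fell (36 and 12 adjusted over the list alone), with Nkx2-2 (2.56, 1.87 to 3.35) and Sox21 (0.79 ± 0.07) among them. Their median was 0.48 (adjusted p = 0.0158). Without the third dTAG-13 library of R that call ended (median 0.49, adjusted p = 0.0508). Counts of that library differed from its replicates with a chi-square of 91.263 and 74.321 per degree of freedom, against 2.251 between those, and its mean log2 CPM was -0.923 for Hox genes against -1.469 and -1.545. Within 1390 Suz12-responsive genes measured, 304 fell and 265 rose (303 and 263 adjusted over the list alone). Their median was 0.02, or 0.01 with absent members at their bound, their mean 0.02, and the test pointed down (adjusted p = 0.767). In all 6354 genes passed, 3278 higher and 3076 lower, with 636 and 710 at 2-fold or more. The datasets shared 2084 higher genes against 793.2 expected (odds ratio 15.6) and 2265 lower genes against 843.8 (odds ratio 21.9).

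In RS of the dataset with SUV2, dTAG13 raised Ube2dnl1 (2.61 ± 0.16), Akr1c18 (1.86 ± 0.18), Aspa (1.51 ± 0.17), the preimplantation genes Pramel7 (2.14 ± 0.23) and Pramel6 (1.91 ± 0.16). The noncoding Lncenc1 (-2.08 ± 0.04), Plac8 (-1.98 ± 0.09), Pla2g1b (-1.98 ± 0.09), Pou2f3 (-1.91 ± 0.16) and Wdr86 (-1.91 ± 0.20) fell. Within 123 developmental transcription factors measured, 20 rose and 24 fell (17 and 22 adjusted over the list alone), with Meis2 (0.58 ± 0.05) and Pou3f2 (1.21 ± 0.12) among them. Their median was 0.01, their mean -0.06, and the test pointed up (adjusted p = 0.965). Of all 1276 Suz12-responsive genes measured, 515 fell and 187 rose (521 and 190 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.00257). Among all 18 p53 targets measured, 15 rose and 1 fell (15 and 1 adjusted over the list alone). Their median was 0.26 (adjusted p = 2.75e-08). In all 7611 genes passed, 3657 higher and 3954 lower, with 193 and 486 at 2-fold or more.

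In RS of the dataset with SD2, the water channel gene Aqp1 (3.51 ± 0.19), the adhesion gene Vcam1 (3.27 ± 0.26), Ube2dnl1 (2.99 ± 0.19), Tdpoz4 (2.58 ± 0.14) and Tdpoz8 (2.49 ± 0.24) rose. The protease gene Ctsh (-2.78 ± 0.27), Lefty2 (-2.75 ± 0.16), Mboat1 (-2.57 ± 0.18), Acsl6 (-2.52 ± 0.20) and Thy1 (-2.52 ± 0.16) fell. Of all 124 developmental transcription factors measured, 32 fell and 17 rose (32 and 17 adjusted over the list alone), with Meis2 (0.85 ± 0.06) and Tbx15 (-1.39 ± 0.12) among them. Their median was -0.19 (adjusted p = 0.603). Among all 1390 Suz12-responsive genes measured, 562 fell and 191 rose (601 and 205 adjusted over the list alone). Their median was -0.29 (adjusted p = 0.00151). Of 19 p53 targets measured, 12 rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 0.31 (adjusted p = 4.79e-05). In all 5804 genes passed, 2414 higher and 3390 lower, with 445 and 822 at 2-fold or more. The datasets shared 1506 higher genes against 511 expected (odds ratio 15.9) and 2361 lower genes against 874.7 (odds ratio 21.9).

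In RS with S12N-SUV2, dTAG13 raised Ube2dnl1 (2.65 ± 0.17), the chromatin remodeller gene Smarca2 (2.42 ± 0.14), Akr1c18 (2.16 ± 0.16), Abat (1.88 ± 0.15) and Anxa8 (1.86 ± 0.16). Card6 (-2.23 ± 0.20), Clstn3 (-2.20 ± 0.07), Tmem54 (-2.08 ± 0.18), Hdx (-2.08 ± 0.17) and Pla2g1b (-2.08 ± 0.08) fell. Among all 123 developmental transcription factors measured, 34 fell and 14 rose (33 and 14 adjusted over the list alone), with Meis2 (0.72 ± 0.05) and Tal1 (-1.19 ± 0.12) among them. Their median was -0.12 (adjusted p = 0.375). Of 1276 Suz12-responsive genes measured, 555 fell and 173 rose (558 and 177 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.000191). Among 18 p53 targets measured, 15 rose and 1 fell (15 and 1 adjusted over the list alone). Their median was 0.40 (adjusted p = 4.16e-08). In all 8326 genes passed, 4077 higher and 4249 lower, with 305 and 680 at 2-fold or more.

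In RS with S12N-SD2, dTAG-13 raised Tdpoz8 (2.49 ± 0.22), Tdpoz4 (2.43 ± 0.12), Lars2 (2.31 ± 0.16), Slc25a34 (2.21 ± 0.15) and Abcb5 (2.21 ± 0.24). Adgrg1 (-2.79 ± 0.26), Lefty2 (-2.51 ± 0.13), Syt7 (-2.43 ± 0.14), Clstn3 (-2.42 ± 0.07) and Slfn9 (-2.24 ± 0.32) fell. Of 124 developmental transcription factors measured, 25 fell and 18 rose (25 and 16 adjusted over the list alone), with Meis2 (0.66 ± 0.06) and Evx1 (-1.06 ± 0.11) among them. Their median was -0.04 (adjusted p = 0.916). Among 1390 Suz12-responsive genes measured, 506 fell and 176 rose (521 and 182 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.00284). Within 19 p53 targets measured, 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 0.60 (adjusted p = 6.47e-10). In all 6307 genes passed, 2817 higher and 3490 lower, with 504 and 763 at 2-fold or more.

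**Figure D4:**
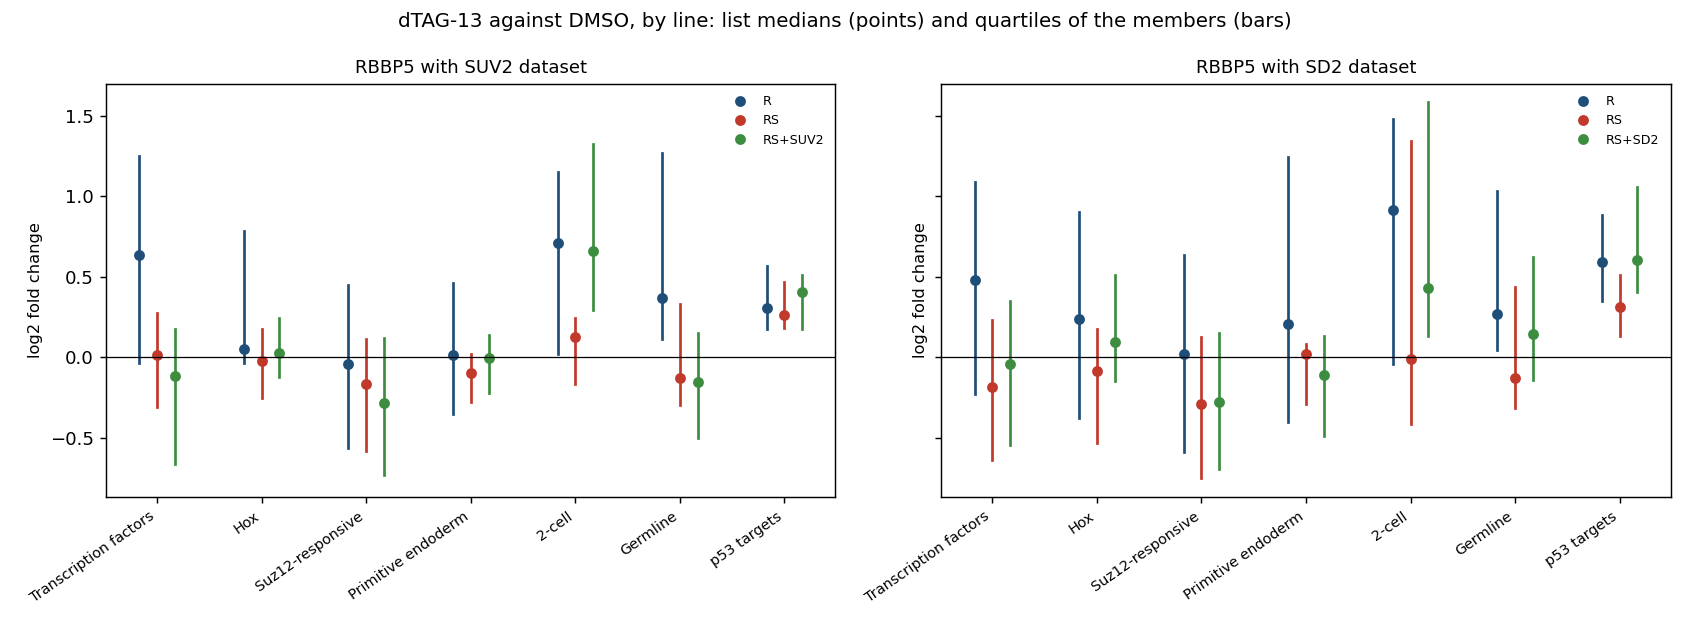
Median log2 fold change (y axis) of dTAG-13 against DMSO for 7 gene lists (points) with the quartiles of their members (bars), by line and dataset. The p53 target medians lie at 0.31, 0.26 and 0.40 with SUV2 and at 0.59, 0.31 and 0.605 with SD2, in R, RS and the fusion line.

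Whether the response to RBBP5 loss differed between lines was tested as an interaction. With SUV2, the response in RS exceeded that in R for Lgals9 (2.34 ± 0.22) and was lower for Fbn1 (-1.83 ± 0.23) and Cntfr (-1.76 ± 0.26). Among 123 developmental transcription factors measured, 7 had a higher and 21 a lower response (7 and 21 adjusted over the list alone), with En2 (-0.89 ± 0.12) and Sox1 (-1.34 ± 0.18) among them. Their median was -0.65 (adjusted p = 0.00027). Within 1276 Suz12-responsive genes measured, 119 had a higher and 210 a lower response (126 and 228 adjusted over the list alone). Their median was -0.17 (adjusted p = 0.0351). That call ended without replicate 2 or 3 of R in dTAG13 (medians -0.154 and -0.165) or replicate 1 of RS in DMSO (-0.145), in DESeq2 (-0.169, adjusted p = 0.0872) and without the list's 2-fold requirement (-0.037, adjusted p = 0.564). In all 3082 genes passed, 1691 higher and 1391 lower, with 103 and 238 at 2-fold or more. Between RS with S12N-SUV2 and RS, the response differed for Muc3 (1.31 ± 0.29) and Kctd15 (-1.33 ± 0.12). Of 24 pluripotency genes measured, 10 had a higher and 2 a lower response (12 and 2 adjusted over the list alone). Their median was 0.11 (adjusted p = 7.33e-06). Within 17 trophoblast markers measured, 0 had a higher and 9 a lower response (0 and 11 adjusted over the list alone). Their median was -0.37 (adjusted p = 7.79e-06). Within 123 developmental transcription factors measured, 3 had a higher and 13 a lower response (4 and 16 adjusted over the list alone). Their median was -0.12 (adjusted p = 0.0927). Of all 1276 Suz12-responsive genes measured, 53 had a higher and 121 a lower response (59 and 138 adjusted over the list alone). Their median was -0.07 (adjusted p = 0.0442). The last call ended in 9 fits without 1 library (medians -0.067 to -0.087), replicates 2 and 3 of the fusion line in DMSO, all 3 of it in dTAG13, 2 and 3 of RS in DMSO, and 1 and 3 of RS in dTAG13, and without the 2-fold requirement (-0.019). In all 1689 genes passed, 799 higher and 890 lower, with 25 and 52 at 2-fold or more.

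With SD2, the response in RS exceeded that in R for Zp3 (2.03 ± 0.30) and Mobp (2.01 ± 0.29). Of all 124 developmental transcription factors measured, 4 had a higher and 23 a lower response (5 and 25 adjusted over the list alone), with En2 (-0.82 ± 0.11) and Sox1 (-1.18 ± 0.17) among them. Their median was -0.59 (adjusted p = 0.000193). Among all 1390 Suz12-responsive genes measured, 74 had a higher and 225 a lower response (89 and 268 adjusted over the list alone). Their median was -0.29 (adjusted p = 0.00457). The last call ended without the list's 2-fold requirement (median -0.107, adjusted p = 0.274). In all 1842 genes passed, 789 higher and 1053 lower, with 167 and 342 at 2-fold or more. Without the third dTAG-13 library of R 3482 passed, with medians of -0.505 and -0.289 for these lists. Between RS with S12N-SD2 and RS, the response differed for Acaa1b (1.66 ± 0.31) and Snx33 (-1.67 ± 0.30). Of all 19 p53 targets measured, 4 had a higher and 0 a lower response (10 and 0 adjusted over the list alone), with Plk2 (0.95 ± 0.11) and Sesn2 (0.52 ± 0.07) among them. Their median was 0.39 (adjusted p = 6.1e-10). Of 15 stress-response genes measured, 3 had a higher and 0 a lower response (6 and 0 adjusted over the list alone). Their median was 0.26 (adjusted p = 1.23e-06). No shift passed for the developmental transcription factors (median 0.04 over 124, adjusted p = 0.681) and Suz12-responsive genes (median 0.04 over 1390, adjusted p = 0.976). In all 314 genes passed, 125 higher and 189 lower, with 24 and 31 at 2-fold or more. Leaving out 1 library gave 191, 209 and 198 for replicates 1, 2 and 3 of RS in DMSO, and 209 and 190 for its replicates 2 and 3 in dTAG-13. It gave 205 and 197 for replicates 1 and 2 of the fusion line in DMSO, and 187 and 188 for its replicates 2 and 3 in dTAG-13. Without the third dTAG-13 library of R 2278 passed, 1236 higher and 1042 lower.

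The degron dataset followed the hours after auxin was added. After 2 h no gene passed in edgeR (295 at an unadjusted p under 0.05, 3 in DESeq2). After 4 h the xenobiotic-response gene Cyp1a1 passed alone (3.55 ± 0.20, adjusted p = 5.37e-08), 38.2 CPM against 3.26 in DMSO. It lies on chromosome 9 from 57687928 to 57703824. After 8 h 5 genes passed, Cyp1a1 (2.89 ± 0.20), the Wnt-responsive Sp5 (1.41 ± 0.21) and Nrp2 (-0.83 ± 0.13), with Kitl (2.22 ± 0.36) and Ets1 (2.22 ± 0.37), both chosen after their values were seen. Without the 24 h libraries 2, 3 and 171 genes passed at 2, 4 and 8 h. The 8 h count was 1 without any replicate of DMSO or replicate 1 or 3 of 8 h and 3 without replicate 2 of 8 h, and the calls of Sp5 and Nrp2 were among those lost. At 8 h DESeq2 called 49 higher and 27 lower, and edgeR without the filter 3 and 0.

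Lists were read at the same times, first at 2 h. Among all 62 developmental transcription factors measured, 0 fell and 0 rose (0 and 0 adjusted over the list alone). Their median was 0.04, or 0.03 with absent members at their bound, their mean -0.05, and the test pointed down (adjusted p = 0.902). No shift passed at 2 h for the Suz12-responsive genes (median 0.04 over 1123, adjusted p = 0.0911), but 1 did without replicate 2 of 2 h (median 0.05). At 4 h both lists passed at the preset correlation. Of 62 developmental transcription factors measured, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was 0.24, or 0.23 with absent members at their bound (adjusted p = 4.61e-06, adjusted p = 0.0876 with an estimated correlation). Of 1123 Suz12-responsive genes measured, 0 rose and 0 fell (1 and 0 adjusted over the list alone). Their median was 0.06 (adjusted p = 0.00371, adjusted p = 0.0878 with an estimated correlation). That call ended without the 2-fold requirement (median 0.025, adjusted p = 0.0812). At 8 h both passed again, as did the germline genes. Among 62 developmental transcription factors measured, 0 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.40 (adjusted p = 1.26e-07, adjusted p = 0.0584 with an estimated correlation). Among 1123 Suz12-responsive genes measured, 2 rose and 0 fell (41 and 0 adjusted over the list alone). Their median was 0.23 (adjusted p = 1.11e-14). Among all 22 germline genes measured, 0 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.31 (adjusted p = 5.02e-06).

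After 24 h Xlr (3.88 ± 0.40), Plac8 (3.45 ± 0.38) and the phospholipase gene Pla2g4a (3.34 ± 0.30) rose, as did Rpph1 (3.81 ± 1.08) and Rmrp (3.33 ± 1.13), RNAs without poly(A) tails, which stood at 0.941 and 0.296 with the third library alone. The 10 most counted genes took 9.148 and 11.298 percent of counts in the first 2 libraries and 5.46 in the third. Casq2 (-1.72 ± 0.28), Nrp2 (-1.65 ± 0.15), Ttc25 (-1.61 ± 0.27), Etv4 (-1.54 ± 0.23) and Manba (-1.51 ± 0.13) fell. Of 22 germline genes measured, 19 rose and 0 fell (20 and 0 adjusted over the list alone), with Dazl (1.72 ± 0.11) and Sohlh2 (1.45 ± 0.14) among them. Their median was 1.39 (adjusted p = 1.66e-13). Within 62 developmental transcription factors measured, 17 rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 0.57, or 0.56 with absent members at their bound (adjusted p = 0.000893, adjusted p = 0.207 with an estimated correlation). Within 1123 Suz12-responsive genes measured, 464 rose and 50 fell (501 and 60 adjusted over the list alone). Their median was 0.70 (adjusted p = 4.42e-16). Among 40 ribosomal protein genes measured, 24 rose and 0 fell (26 and 0 adjusted over the list alone). Their median was 0.72 (adjusted p = 9.26e-07, adjusted p = 0.56 with an estimated correlation). Among 24 H3K9 and H3K36 methylation writers and readers measured, 5 fell and 0 rose (5 and 0 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.00644, adjusted p = 0.491 with an estimated correlation). In all 4805 genes passed, 2295 higher and 2510 lower, with 1368 and 112 at 2-fold or more. RLE size factors gave 2676 higher and 1794 lower, and DESeq2 2955 and 2034. Without the third 24 h library 8472 passed, and the transcription factor call ended (median 0.51, adjusted p = 0.116). With it as the only 24 h library, 1 sample whose spread had to be taken from other groups, the medians were 1.09 for transcription factors, 1.63 for germline, 0.83 for Suz12-responsive, -0.24 for ribosomal protein and 0.103 for H3K9 and H3K36 genes, and Etv4 was at -0.944.

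After 48 h Rhox13 (6.44, 5.53 to 7.74), Krtdap (6.08 ± 0.38), Crispld2 (5.98, 5.41 to 6.70), Zfp703 (5.38, 4.67 to 6.26) and the matrix gene Fbln2 (4.68, 4.09 to 5.40) rose. Ubap1l (-3.39 ± 0.22), Got1l1 (-3.33 ± 0.24), the hypoxia-responsive Ndufa4l2 (-3.28 ± 0.34), Tspo2 (-3.18 ± 0.25) and Dnajc5g (-3.15 ± 0.19) fell. Of all 62 developmental transcription factors measured, 37 rose and 5 fell (39 and 6 adjusted over the list alone), with Tbx15 (1.42 ± 0.15) and Tlx2 (3.62, 3.02 to 4.34) among them. Their median was 1.20 (adjusted p = 6.48e-07, adjusted p = 0.0699 with an estimated correlation). Among 12 mesoderm genes measured, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with Cdx1 (2.86 ± 0.17) and Wnt3 (3.90, 3.08 to 4.93) among them. Their median was 2.54 (adjusted p = 0.00155). Of all 1123 Suz12-responsive genes measured, 540 rose and 129 fell (569 and 136 adjusted over the list alone). Their median was 0.76 (adjusted p = 3.03e-11). Of 14 glycolysis and hypoxia genes measured, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with Pdk1 (-2.19 ± 0.13) and Aldoa (-1.43 ± 0.12) among them. Their median was -0.94 (adjusted p = 2.39e-05). In all 6170 genes passed, 2831 higher and 3339 lower, with 1540 and 1016 at 2-fold or more. With the panel's knockout 997 higher genes were shared against 573.2 expected (adjusted p = 5.11e-104, Fisher's exact test, odds ratio 2.93) and 975 lower genes against 836.8 (adjusted p = 1.74e-10, odds ratio 1.35). DMSO was sampled at 48 h only, so hours of culture and hours of auxin are not separated at earlier times.

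**Figure D5:**
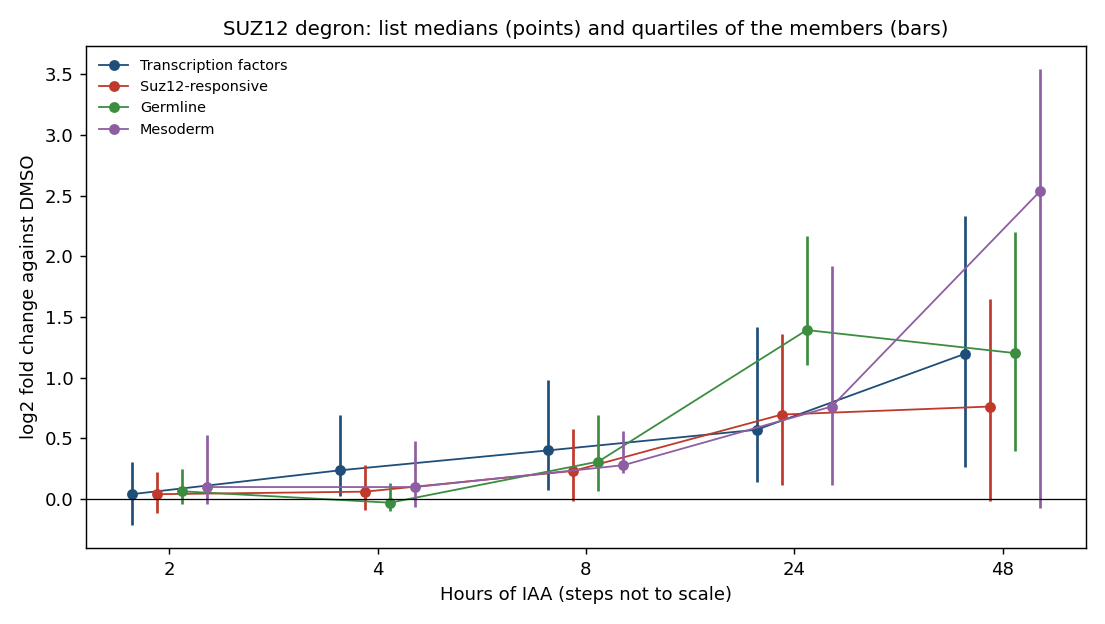
Median log2 fold change against DMSO (y axis) of 4 gene lists (points) with the quartiles of their members (bars) after 2, 4, 8, 24 and 48 h of auxin. The median of the developmental transcription factors was 0.04, 0.24, 0.40, 0.57 and 1.20.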

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

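All tests of explanations in this part were chosen after the results were seen, except the counts of splits, which were planned.

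The response to RBBP5 loss differed between lines by a test of the difference itself. With SUV2, 3082 genes differed between RS and R, with medians of -0.652 for the developmental transcription factors and -0.17 for the Suz12-responsive genes. Between RS with S12N-SUV2 and RS 1689 genes differed, with a Suz12-responsive median of -0.075. With SD2 the counts were 1842 between RS and R, with medians of -0.586 and -0.293 for the same lists, and 314 between RS with S12N-SD2 and RS. Of 25 splits each, 4, 3, 4 and 3 gave as many genes, the real ones included, and the highest others gave 8355, 4111, 5715 and 2565. These splits mixed the lines unequally, so a structure of the samples, the difference between lines, entered them. Among the 7 splits of each that mixed the lines equally the highest count was 0. Groups in those held both lines, whose difference widened the spread within them. A low count would follow with or without an interaction, so these 7 do not decide.

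Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In 1 of the 10, the real one, the count was as large in every such comparison except those at 2 h and 24 h of the degron. The highest other was 460 for the dead SD2 fusion against S12N (2123 in the real split), 396 for dTAG-13 in R with SD2 (6354), 61 for the HP1 fusion (978) and 4 or fewer elsewhere. At 2 h the real count was 0 in edgeR (295 at an unadjusted p under 0.05, 3 in DESeq2), and 10 of 10 splits gave as many. At 24 h 2 of 10 did, and the highest other (6105 against 4805) set the third 24 h library with DMSO replicates 1 and 2 against the remaining libraries.

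The 24 h comparison called 4805 genes, those of 2-fold or more mostly higher. Of 8423 genes called from the first 2 libraries, 49.7 percent moved the same way in the third, against 34.7, 69.6 and 55.5 in the 2 h libraries, where no gene passed, which is consistent with a change carried by the first 2 libraries alone for many genes. Genes 2-fold higher had a median exon length 0.756 times that of all tested genes (3211 against 4247), which does not decide whether short transcripts were over-represented. Correlations of change with length (across genes, which are not independent replicates) were -0.304, -0.354 and 0.265 in the 24 h libraries and 0.36, -0.132 and -0.324 in DMSO. Loss of SUZ12 remains open as the biological explanation.

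In the RBBP5 dataset with SD2, Meg3 had 4, 0 and 1 counts in RS in DMSO. The tables argue against genes left uncounted, as Meg3 was higher by 10.13 in the S12N-SD2 line, and against loss of the domain with Dlk1 from both chromosomes, as Dlk1 was higher by 1.29 ± 0.152 in RS than in R. Meg3 was under 1 CPM in 6 of 6 RS and 0 S12N-SD2 libraries. That argues against 1 wrong label or a partial swap, but a swap of whole lines would look alike. RS read as labelled in Suz12 (59.3 CPM against 325 in R) and shared 2361 lower genes with the other dataset's RS after dTAG13. Outside libraries would then have to be of a like line. That, a whole swap and a loss sparing the expressed copy of Dlk1 stay open. So does the knockout, though S12N-SD2, one too, had Meg3 at 114 to 117 CPM in DMSO.

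In the HP1 dataset, 3 Y-linked genes had 1 count in the 3 S12N libraries together. At the level of the knockout 4802 were expected, which argues against depth. 0 other libraries under 10 such counts argue against a partial swap, not one of whole groups. Only 265 genes differed from the knockout, and Suz12 was higher by 0.99, so outside libraries would have to be of a like line. That, a whole swap and loss of the Y stay open, and no biological explanation was tested.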

How the results depend on the processing

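The thinned counts, the fits without the 24 h libraries, with the third 24 h library alone (1 sample, its spread taken from other groups), without the third dTAG-13 library of R, with replicates 1 and 2 only and without rRNA-like genes, and the overlaps under each setting, were chosen after seeing the data. Of the counts under all alternatives 313 stayed within 1.5 times and 53 did not. Of single named genes 5718 values kept their side of the threshold, 237 lost it, 47 gained it and 2 reversed. Of the overlaps 71 stayed and 1 moved. The cause was not tested for the values below unless fewer libraries or genes are the alternative itself.

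Thinning gave 2334 for SUV2, 1934 for SD2 and 1363 for the dead SD2 fusion against S12N. Without the third dTAG-13 library of R, 3482 and 2278 genes passed for the interactions of RS with R and of RS with S12N-SD2 with RS, and 6652 for S12N-SD2 against RS. DESeq2 gave 593 for the interaction of S12N-SD2. In the degron, DESeq2 gave 3, 6 and 76 at 2, 4 and 8 h, and fits without the 24 h libraries 2, 3 and 171. At 8 h, RLE size factors gave 9, no low-count filter 3 and the replicate block 1. Replicates 1 and 2 only gave 1634 for the HP1 fusion. The shared higher genes of S12N rose from 14 to 33 with no filter.

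With 1 library left out, counts ran from 1054 to 1616 for the rescue against wild type, 332 to 534 for S12N in the panel, 2251 to 2908 and 1371 to 2077 for the dead SUV2 and SD2 fusions, and 1699 to 2925 for SD2. They ran from 1312 to 3482 and 187 to 260 for the SD2 interactions, 1 to 3 and 3509 to 8472 at 8 and 24 h, 129 to 217 for S12N in the HP1 dataset and 430 to 1492 for the HP1 fusion. The transcription factor medians ran from 0.445 to 0.551 for dTAG-13 in R with SD2, from -0.202 to -0.097 for S12N-SD2 and from 0.509 to 0.806 at 24 h. The Suz12-responsive medians ran from 0.113 to 0.146 for the dead SUV2 fusion, -0.193 to -0.145 and -0.088 to -0.067 for the SUV2 interactions, 0.022 to 0.051 at 2 h and 0.098 to 0.166 for the HP1 fusion.

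With an estimated correlation, calls ended for Suz12-responsive medians of -0.161 (S12N), 0.131 (dead SUV2), -0.156 (SD2), 0.061 (4 h) and 0.128 (HP1 fusion). So did those for transcription factor medians of 0.634 (dTAG13 in R with SUV2), -0.404 (S12N-SUV2), -0.174 (S12N-SD2) and, at 4, 8, 24 and 48 h, 0.237, 0.401, 0.571 and 1.197. DESeq2 gave -0.169 for the Suz12-responsive list in the interaction of RS with R and -0.115 for transcription factors in that of S12N-SUV2, a call gained, as with no filter (-0.155). For S12N-SD2 the transcription factor call ended with no filter (-0.094) and without the third dTAG-13 library of R (-0.175), and for dTAG-13 in R without that library (0.491). Without the 2-fold requirement the Suz12-responsive medians that lost their call were -0.037, -0.019, -0.107 and 0.025, in the interactions with SUV2, of RS with SD2 and at 4 h, and this broader list had smaller medians in the knockouts too (0.635 in the panel, 0.754 in the HP1 dataset).

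Reversed were the ribosomal protein median of the SD2 interaction of RS (-0.319, from -0.436 to 0.024 with 1 library left out, the latter without the third dTAG-13 library of R) and, with the third 24 h library alone, those of the H3K9 and H3K36 list (0.103), of ribosomal proteins (-0.24) and Kdm4a (0.346). Without that library Setd2 reversed (-0.586 to 0.32 with 1 library left out). In the degron, with a common biological coefficient of variation of 0.169, the simulation recovered 5 percent of changes of 0.5 at 2 h.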

Other observations

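Both tests in this part were chosen after the result was seen. Genes lower with an active fusion in the panel were hypothesised to be lower with the same fusion in the RBBP5 line. For SD2, 377 were lower in both against 220.2 expected (odds ratio 2.2, p = 2.83e-30, Fisher's exact test), and for SUV2 1307 against 492.6 (odds ratio 8.89). Among higher genes the odds ratios were 2.73 and 6.04. Genes are not independent replicates, the compared lines differ in their controls, and Suz12 was lower with the active fusions in the panel (-0.393 for SUV2, -0.965 for SD2) and higher in the RBBP5 lines (1.652 and 0.431).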
